A study of Homo sapiens with 4 samples.

How the data were processed

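ATAC-seq was performed on BCPAP cells without treatment (2 libraries) and after 5-azacytidine (2 libraries), per the labels. The labels give paired-end reads of 101 bases and a target of 2 Gb of sequence per sample, and no dose or duration of treatment. The submitters' processing notes name Trimmomatic, Bowtie2, Picard, MACS2 and the hg19 build. Their versions, settings and the filters applied are not given in the sources used here, nor is whether read ends were shifted for the transposase. The contig names in the files are those of hg19.

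Each library has 1 deposited peak list in narrowPeak layout, and peaks were called per library, as the peak names in the files show. Nearly all intervals were 500 bp wide in the deposited lists (2 or 3 intervals per list were not), so the authors had set them to a fixed width. The offset of the summit exceeded 500 in 9.70% to 18.2% of peaks, so it was kept from the original peak. It was used only to check that the centre of an interval is the summit: in each list, all original peaks with several summits (12309 to 19026 per list) gave the same start from every centre minus its offset. The peak score in the deposited lists had been scaled by the authors to a total of 1000000 per list. The fold enrichment and the −log10 p and q values in the deposited lists are the peak's own values as the authors' peak caller gave them. They were used here to describe, rank or filter peaks within a list. The summit coverage derived from the fold was also set side by side between lists, without scaling. In each list at least 99.99% of the fold values were whole multiples of 1 step (within 0.001 of a step), and at least 99.8% of the p-values were those of a Poisson distribution with 1 constant mean. The step therefore gave the uniform background coverage of each library, and each fold value gave the read coverage at the summit, which was 4 or more in every list. The background coverage is proportional to reads times their extended length over genome size, so it compares depth between libraries only if those settings were shared. The number of reads itself is unknown. The peak numbers in the lists have gaps: between 20685 and 36194 numbers were missing per list on the chromosomes used, for reasons not given in the sources used here.

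Peaks on chromosomes 1 to 22 and X were used. Peaks of the 4 lists that shared at least 1 bp were merged to regions, and a region counted as present in a list with at least 1 peak there. Similarity was the Jaccard index of bases. Group values are means with SD over 2 libraries, compared by an exact two-sided permutation test over the 6 assignments of 4 libraries. Counts of regions were set against the crossed classes from the other 2 ways of splitting the 4 libraries in pairs. No test per region was run: the presence of a peak in 2 libraries against 2 cannot pass a threshold, and summit coverage was compared between lists by description only. Shares carry 95% Wilson intervals, and differences of shares Newcombe intervals, for counting error only. Log ratios over windows had 1 added to each count. The 20000, 100000 or 221110 strongest peaks of a list were taken by the authors' p-value, with ties broken at random with a fixed seed. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The merging was tested on simulated lists with 3000 gained and 2000 lost regions, of which 100.0% of each were recovered. The simulated sites lay too far apart to merge with a neighbour. The test therefore checks the counting of patterns only, not the merging of peaks that lie close together.

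Groups, comparisons, most alternatives and the rule for named regions were fixed before the data were examined. The rule takes the 5 gained and 5 lost regions with the best rank percentile by p-value, using the worse of the 2 libraries. The alternatives were an equal number of peaks per list, a −log10 q of at least 5, a merging distance of 150 bp, an overlap of at least 50% of both peaks, the replicate block and leaving out each library. A summit with 100 bp on either side, the strong regions with a coverage of at least 10, the shorter lists of strongest peaks, the exclusion of regions with a missing peak number, the windows and the analysis of chromosome ends were added after seeing the data. These settings were picked after several others had been looked at: lowest coverages from 4 to 20, other numbers of strongest peaks up to nearly the full lists, and windows of 1, 5 and 10 Mb. The replicate numbers do not mark a shared batch in the labels, so they were not used to pair libraries in the main comparison. The planned comparisons of promoters, of 14 gene lists, of gene location and of sequence content were not run, because they need gene positions or sequence on hg19 and the gene table at hand was on another build. Intervals of summits with 250 bp on either side are the deposited intervals themselves, so that alternative could not change a value.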

Results

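Chromatin accessibility was profiled by ATAC-seq in BCPAP cells, an established human thyroid cancer line, with and without the demethylating agent 5-azacytidine. In ATAC-seq a transposase inserts sequencing adapters into exposed DNA, so that accessible sites appear as peaks of read coverage. 5-Azacytidine is a cytidine analogue that traps DNA methyltransferases and lowers CpG methylation. There were 2 untreated and 2 treated libraries, each with its own peak list on the hg19 build. The labels do not say that replicates came from separate cultures, so the spread between them may be technical. On chromosomes 1 to 22 and X the lists held 221110 and 223345 peaks in untreated replicates 1 and 2, and 259572 and 245142 peaks in treated replicates 1 and 2. The number of reads is unknown. The uniform background coverage behind the fold values was 0.913 and 0.898 in the untreated libraries and 0.898 and 0.875 in the treated libraries, so it differed little between them.

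The first comparison addressed the number of peaks and the bases they covered with and without 5-azacytidine. The treated lists held more peaks, with a mean of 252357 ± 10204 (SD, n = 2) against 222228 ± 1580 (SD, n = 2), a difference of 13.6%. Peaks covered 124 ± 5.77 Mb of the genome in treated cells and 109 ± 0.554 Mb in untreated cells (SD, n = 2 each). Both treated libraries lay above both untreated libraries for each measure. Nearly all intervals were 500 bp wide, so the bases covered follow the number of peaks and are not a separate measure. The exact two-sided permutation test gave p = 0.333, the smallest value that 2 libraries against 2 allow, so neither difference could pass a threshold. Treated replicate 1 had the most weak peaks. Peaks with a summit coverage of 6 or less numbered 51659 and 66503 in the untreated lists and 116925 and 73391 in the treated lists. Peaks with a summit coverage of at least 10 numbered 127203 and 111677 in the untreated lists, against 81178 and 115284 in the treated lists. At a −log10 q of at least 5 the order of the groups turned, with a treated mean of 111469 ± 24353 and an untreated mean of 129900 ± 10954 peaks (SD, n = 2 each). This rested on treated replicate 1, with 94249 peaks, since treated replicate 2 had 128689 and lay between the untreated libraries, with 137646 and 122154.

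**Figure D1:**
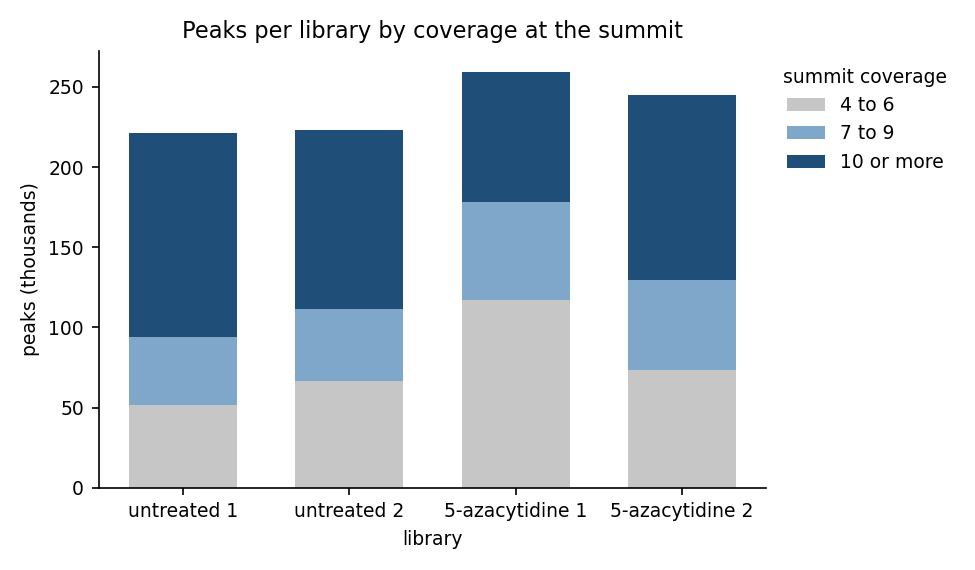
Number of peaks on chromosomes 1 to 22 and X (y axis, in units of 1000 peaks) in each of the 4 libraries (x axis), stacked by read coverage at the peak summit. Treated replicate 1 had 116925 peaks with a coverage of 6 or less, and 81178 with 10 or more, the fewest of the 4 libraries.

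Peaks of treated replicate 1 were the lowest. In the 105414 regions found in all 4 lists, the median summit coverage was 23 and 18 in untreated replicates 1 and 2, and 11 and 16 in treated replicates 1 and 2. The similarity of peak sets was measured as the Jaccard index, the bases in both lists over the bases in either. It was 0.454 between the untreated libraries and 0.339 between the treated libraries. Between groups it was 0.331 and 0.409 for untreated replicate 1 against treated replicates 1 and 2, and 0.325 and 0.389 for untreated replicate 2 against them. The treated pair was therefore less alike than treated replicate 2 and either untreated library. Among the 20000 strongest peaks of each list, a comparison chosen after the data were seen, the order was different. The index was 0.616 within the untreated pair and 0.539 within the treated pair, against 0.478 to 0.526 between groups, so that the libraries of each group were closest to each other.

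The second comparison asked which regions became accessible or closed under treatment. Merging the peaks of the 4 lists gave 373425 regions, of which 28.2% were in all 4 lists and 45.9% in 1 list only. A gained region had a peak in both treated lists and in neither untreated list, and a lost region had the reverse. There were 15707 gained and 12522 lost regions. Regions shared by 1 untreated and 1 treated list and absent from the other 2 show how many regions fall into such patterns without the treatment separating them. These 4 crossed classes held 6321 to 9026 regions each, so that the gained regions were 1.74 times and the lost regions 1.39 times as many as the largest of them. Gained regions pair the 2 longest lists, so these ratios may also reflect list length. With the same number of peaks in each list they were 1.26 and 1.80. At 24.4% of gained, 26.1% of lost and 27.0% to 28.1% of crossed regions, a list counted as without a peak lacked a peak number at that place. A called peak may have been removed there. Leaving such regions out gave 11877 gained and 9258 lost regions, and 6581 in the largest crossed class. The presence of a peak in 2 libraries against 2 cannot pass a threshold for any single region, and coverage in shared regions was not tested. Leaving out a library removes a condition and raised the counts by construction. It also tilts the balance of the classes. Without an untreated library a lost region needs a peak in 1 list and a gained region in 2, and the reverse holds without a treated library. Which class was larger in these settings therefore says nothing about the treatment. Gained and lost regions were 24237 and 42217 without untreated replicate 1, 22966 and 41225 without untreated replicate 2, 56747 and 19661 without treated replicate 1, and 87730 and 28607 without treated replicate 2.

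Regions found in 2 lists were mostly low peaks. The median summit coverage was 6 in each treated library for gained regions and 7 in each untreated library for lost regions. A coverage of 10 in both lists was reached by 3.30% of gained, 7.75% of lost and 0.489% to 3.18% of crossed regions. In regions of all 4 lists the median was 11 in treated replicate 1 against 23 and 18 in the untreated libraries. A fixed coverage is therefore not an equal limit for gained and lost regions. Which class was larger depended on peak strength. Where lists were shortened, by number or by q, a region counted as absent from a list may have a weaker peak in the deposited list. With the same number of peaks in each list, the 221110 strongest, 10861 regions were gained and 15472 lost, and the largest crossed class held 8609. At a −log10 q of at least 5, with weaker peaks left out of every list, 3382 regions were gained and 10431 lost. There the gained regions were fewer than the 6112 shared by untreated replicate 1 and treated replicate 2 alone, the libraries with the most peaks at that threshold. Among strong regions, with a coverage of at least 10 in both lists and no listed peak in the other 2, 519 were gained and 971 lost, against 36 to 287 in the crossed classes. Among the 20000 strongest peaks of each list the gained and lost regions were nearly equal, at 1605 and 1641, and each class was about 3 times the largest crossed class of 546. All these peaks had a coverage of at least 20. Only 15 gained and 21 lost regions of that coverage had no listed peak in the other lists. Nearly all of the 1605 and 1641 regions therefore had a weaker listed peak in another list.

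**Figure D2:**
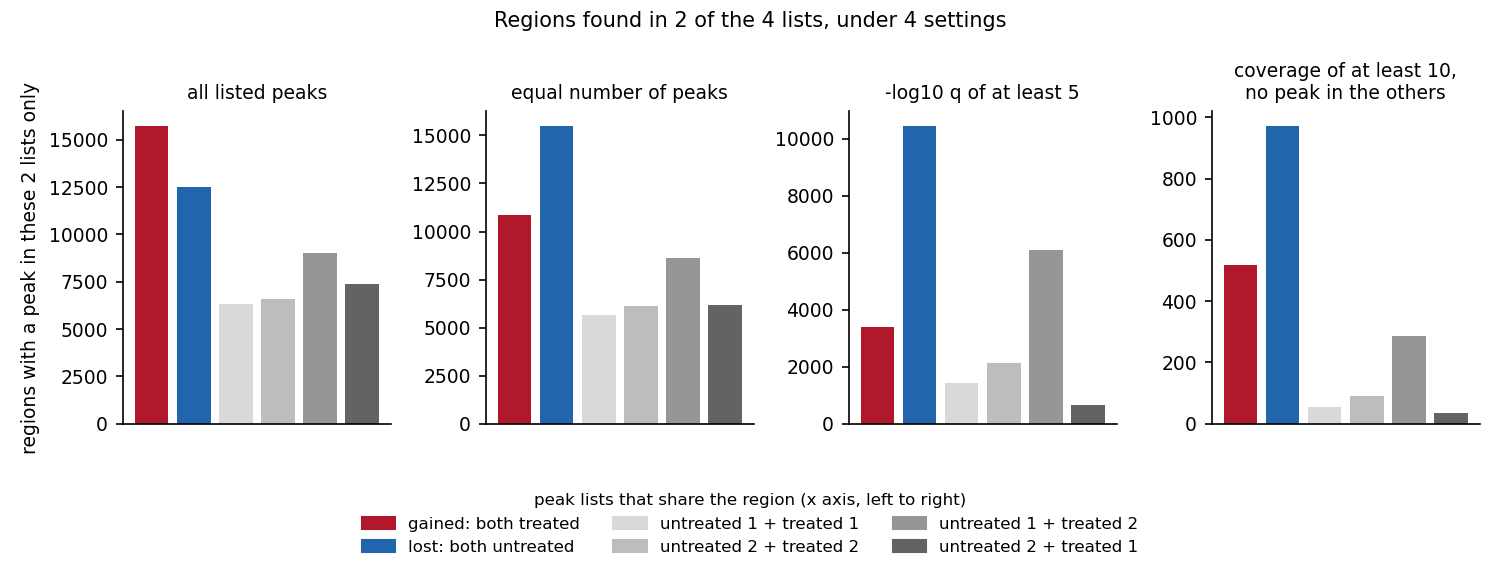
Number of regions (y axis, from 0, a separate scale per panel) with a peak in exactly 2 of the 4 lists, for gained and lost regions and the 4 crossed classes (bars), under 4 ways of choosing peaks (panels). Gained regions outnumbered lost regions with all listed peaks, 15707 against 12522, and not in the other 3 panels. In the panels with an equal number of peaks and with a −log10 q of at least 5, weaker peaks left out by the choice do not count as present.

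The strongest gained region lay on chromosome 19 from 38663879 to 38664394 (hg19), with a summit coverage of 36 and 45 in treated replicates 1 and 2. The authors' fold enrichment there was 19.5 and 24.5, and no peak was listed in either untreated library. On chromosome 17, the region from 74692808 to 74693339 had a coverage of 21 and 41. The region from 891170 to 891697 on chromosome 5, near the end of its short arm, had a coverage of 21 and 33. Chromosome 16 from 83739952 to 83740460 reached 30 and 31, and chromosome 11 from 87002838 to 87003355 reached 23 and 30. In none of these was a peak number missing from the untreated lists at that place.

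The strongest lost region lay on chromosome 1 from 94572220 to 94572745, with a coverage of 43 and 29 in untreated replicates 1 and 2 and no peak in the treated lists. It was followed by chromosome 1 from 221875044 to 221875560, with 38 and 28. On chromosome 10, the region from 90025717 to 90026226 had a coverage of 39 and 28, and that from 63587931 to 63588439 had 38 and 24. Chromosome 3 from 76183295 to 76183804 had 34 and 24. For the first of the chromosome 10 regions and for the chromosome 3 region, a peak number was missing from a treated list at that place, so a called peak may have been removed there. The genes at these positions were not analysed here, since no hg19 annotation was used.

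Some windows of 1 Mb held several strong gained regions. Chromosome 12 held 7 of them between 132 and 133 Mb, and no lost or crossed region of that strength. Chromosome 11 held 6 between 2 and 3 Mb, chromosome 4 held 6 between 7 and 8 Mb, and chromosome 1 held 5 between 41 and 42 Mb, beside 1 lost region. Strong lost regions were densest on chromosome 19 between 6 and 7 Mb, with 5 lost and 2 gained, and on chromosome 9 between 72 and 73 Mb, with 4 lost and 0 gained. These windows were chosen by their counts after the data were seen, and the counts were not tested against chance.

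The third comparison was of chromosomes. Gained regions made up the largest share of a chromosome's regions on chromosome 19, at 5.85% (95% Wilson interval 5.47 to 6.26). Chromosomes 16 and 20 followed, each at 5.32% (4.90 to 5.78 and 5.00 to 5.66), then chromosome 17 at 4.96% (4.64 to 5.30) and chromosome 11 at 4.81% (4.56 to 5.07). The lowest shares were on chromosome 8, at 2.94% (2.63 to 3.27), and chromosome X, at 3.03% (2.66 to 3.45). Lost regions were most frequent on other chromosomes. They made up 5.10% (4.70 to 5.53) on chromosome 8, 4.78% (4.33 to 5.27) on chromosome 13 and 4.66% (4.36 to 4.98) on chromosome 4, but 1.89% (1.69 to 2.10) on chromosome 20 and 2.37% (2.20 to 2.56) on chromosome 11. Chromosome 20 had 2.82 gained regions for each lost region, chromosome 19 had 2.30, and chromosome 8 had 0.576. The intervals cover counting error only, and regions are not replicates. The order of the 23 chromosomes was similar among strong regions (Spearman rho 0.83 between the settings) but not among the 20000 strongest peaks (rho −0.01). In that last setting nearly all gained and lost regions had a weaker listed peak in another list, so it counts other regions than the full lists. Its log2 ratio of gained to lost regions, relative to all chromosomes, was −1.42 on chromosome 19, against 0.87 in the full lists. It was −0.99 against 0.47 on chromosome 16 and −1.19 against 0.44 on chromosome 17. On chromosome 4 it was 0.30 against −0.68, and on chromosome X 0.07 against −0.90. Chromosomes 20 (0.56), 11 (1.07), 8 (−0.11) and 13 (−0.05) had the same sign in both settings.

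**Figure D3:**
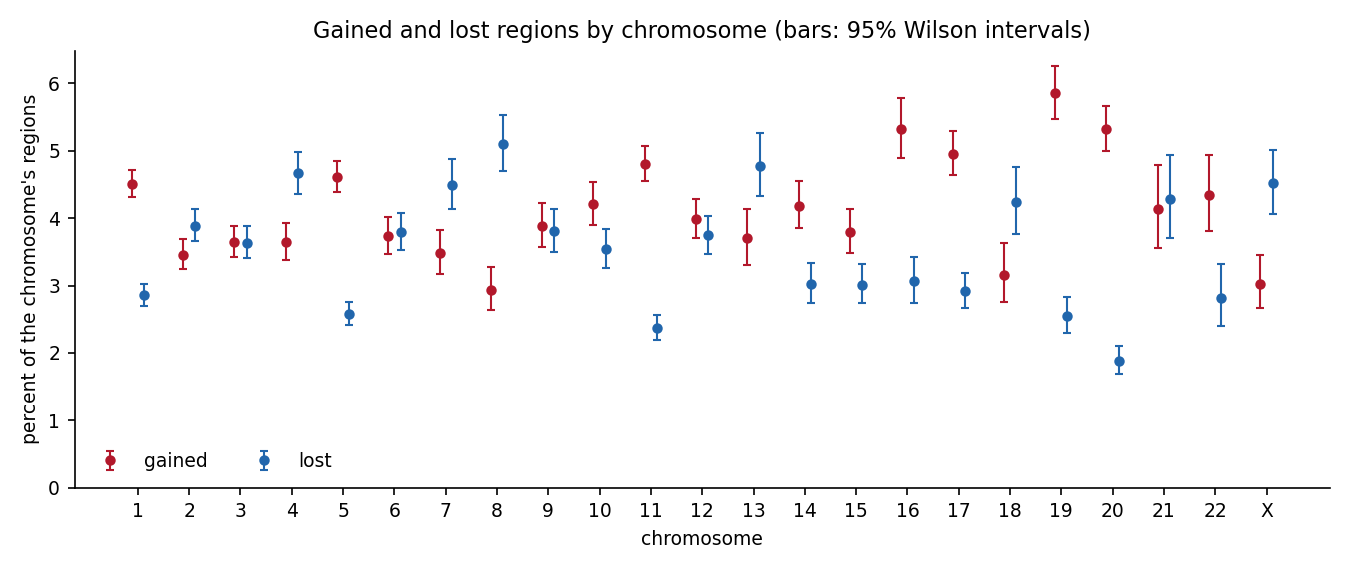
Gained and lost regions as a percentage of all regions on each chromosome (y axis, from 0), for chromosomes 1 to 22 and X (x axis), with 95% Wilson intervals for counting error. Gained regions reached 5.85% on chromosome 19, and lost regions 5.10% on chromosome 8.

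The crossed classes were unevenly spread over chromosomes as well. Regions shared by untreated replicate 2 and treated replicate 1 alone made up 3.78% of regions on chromosome 20 and 0.991% on chromosome 8. Those shared by untreated replicate 1 and treated replicate 2 alone made up 1.72% and 3.54% there. Over 571 windows of 5 Mb with at least 100 regions, the log2 ratio of gained to lost regions was set against the log2 ratio of these 2 crossed classes. Pearson's r was 0.69 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 3e-05 over 3 relations) and Spearman's rho 0.71 (p = 1e-05, adjusted 3e-05), and r was 0.69 without the 2 windows farthest from the median. The ratio of the other pair of crossed classes gave r = 0.11 (permutation p = 0.0091, adjusted 0.0091) and rho = 0.13 (p = 0.0023, adjusted 0.0023). The number of regions in all 4 lists per window gave r = 0.50 and rho = 0.48 (permutation p = 1e-05, adjusted 1.5e-05 for each). Windows are not independent replicates, and the ratios share libraries: built from regions in 1 list only, the same ratios as in the first relation gave a rho of 0.68. In the 2 windows with the highest ratios the crossed classes went the other way. Chromosome 11 between 80 and 85 Mb held 12 gained and 0 lost regions, with 1 region shared by untreated replicate 2 and treated replicate 1 alone and 9 shared by untreated replicate 1 and treated replicate 2 alone. Chromosome X between 135 and 140 Mb held 8 gained and 0 lost regions, with 2 and 7 in these crossed classes. In the next 3 they went the same way. Chromosome 15 between 20 and 25 Mb held 23 gained and 2 lost regions, with 11 and 3 in the crossed classes. The first 5 Mb of chromosome 4 held 174 gained and 23 lost regions, with 84 and 23 in the crossed classes, and the end of chromosome 20 from 60 Mb held 114 and 15, with 105 and 19. The lowest ratio was on chromosome 4 between 90 and 95 Mb, with 1 gained and 20 lost regions and 1 and 7 in the crossed classes.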

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

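The tests of both results here, which concern contigs outside the comparisons, were chosen after the result was seen. On the unplaced contig chrUn_gl000220, which carries ribosomal RNA gene sequence, the untreated lists held 78 and 86 peaks and the treated lists 117 and 101, a ratio of means of 1.33. On the contig chr7_gl000195_random, assigned to chromosome 7 without a position, the untreated lists held 46 and 59 peaks and the treated lists 85 and 66, a ratio of 1.44. These 2 contigs were the only ones outside the chromosomes used, chromosome Y left aside, with at least 20 peaks in every list. On both, each treated list was above both untreated lists, as it was for the peaks on chromosomes 1 to 22 and X, with a ratio of 1.14. All peaks outside those chromosomes numbered 232 and 305 in the untreated lists and 497 and 303 in the treated lists. There the groups overlapped, since treated replicate 2 lay just below untreated replicate 2. The order of the groups on the 2 contigs was thus shared with chromosomes 1 to 22 and X, at a lower ratio, but not with all other contigs together.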

How the results depend on the processing

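The tests with the 100000 and 20000 strongest peaks, strong regions, summits with 100 bp on either side, missing peak numbers and chromosome ends were chosen after the result was seen. The counts of regions depended on how strong a peak had to be. With shortened lists or a stricter q, peaks left out by the setting did not count as present. At a −log10 q of at least 5, the log2 ratio of treated to untreated peaks turned from 0.18 to −0.22 and that of bases covered from 0.19 to −0.22. With an equal number of peaks per list the log2 ratio of bases covered was 0.0036, since nearly all intervals had the same width. The 3382 gained regions at that q, 4918 among the 100000 strongest peaks, 1605 among the 20000 strongest and 519 strong regions compare with 15707 in the full lists. Lost regions numbered 5878, 1641 and 971 in the last 3 settings against 12522. The log2 ratio of gained to lost regions was 0.33 in the full lists and turned to −0.51 with equal numbers, −1.62 at the stricter q, −0.26 and −0.032 among the 100000 and 20000 strongest, and −0.90 among strong regions. It kept its sign with a 150 bp merging distance (0.24), an overlap of at least 50% (0.14) and summits with 100 bp on either side (0.022). It also did so without the regions with a missing peak number (0.36). With equal numbers the lost regions rose to 15472. That setting removed peaks mainly from the treated lists, which were longer. Regions whose treated peaks were all removed then counted as lost by construction. The cause of the other changes was not tested. Leaving out 1 library gave 22966 to 87730 gained and 19661 to 42217 lost regions, a log2 ratio of −0.84 to 1.62. The sign of that ratio follows from the definition, since the class of the group left with 1 library needs a peak in 1 list only. The log2 ratio of bases covered was 0.14 to 0.24 in these settings. With the replicate block, the mean of paired log2 ratios was 0.18 for peaks and 0.19 for bases, and changed no direction. The mean Jaccard index within groups exceeded that between groups by 0.033, and by 0.076 among the 20000 strongest peaks. In the full lists this rested on the untreated pair, at 0.454. The treated pair, at 0.339, lay below treated replicate 2 against untreated replicates 1 and 2, at 0.409 and 0.389. The number of chromosomes with more gained than lost regions relative to the genome was 10, and 6 among the 100000 strongest peaks. The share of chromosomes 17 and 19 among the strongest peaks, lower in treated lists by 0.73 and 0.93 percentage points, turned to 0.14 and 0.29 over all peaks, and for chromosome 19 to 0.0835 among the 100000 strongest. That of chromosome 5, higher by 1.30, was higher by 0.885, 0.762 and 0.897 among the 50000 and 100000 strongest and all peaks. The excess of gained over lost regions near chromosome ends was 11.6 percentage points, 6.52 within 2 Mb, 13.5 within 10 Mb, 19.6 among strong regions, 11.6 and 14.6 among them without treated replicates 1 and 2, and 0.19 among the 20000 strongest peaks. Promoters, gene lists, location and sequence were not run for want of hg19 positions. A region without a listed peak is one where no peak was called or a peak was removed from the list, not one shown to be closed.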

Other observations

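All tests in this part, except the comparison of all gained regions near chromosome ends with the class of untreated replicate 2 and treated replicate 1, were chosen after the result was seen, and several were revised after their outcome. The test of strong regions near the ends was added once that earlier comparison had not excluded background, and it first pooled the 4 crossed classes. The reference from regions in 1 list was added to the test over windows later. A test of peak height over all chromosomes came out undecided and was followed by separate tests for chromosomes 17 and 19 and for 5 and 11. A looser limit was tried for the latter pair and a counting interval alone for the former, and both are judged here by stricter limits. The test of copies of chromosomes 5 and 11 first asked only for a gap above 0, which was met, and its counting interval was added later. A larger share of gained than of lost regions lay near the ends of chromosomes, although most gained regions did not. Of the 519 strong gained regions, 26.2% (95% Wilson interval 22.6 to 30.2) were within 5 Mb of the outermost peak of a chromosome arm, leaving out the short arms of chromosomes 13, 14, 15, 21 and 22. The share was 6.59% (5.20 to 8.33) of the 971 strong lost regions and 9.78% (9.53 to 10.02) of strong regions in all 4 lists. It was higher for gained than for lost regions on 20 of 23 chromosomes. On chromosome 11, 17 of 44 strong gained regions were near an end and 3 of 31 lost regions, and on chromosome 17 these were 14 of 25 and 7 of 32. Without treated replicate 1 the shares were 19.1% for gained and 7.52% for lost regions, and without treated replicate 2 they were 21.6% and 6.998%. In strong regions found in 1 list only, the share was 5.55% (4.56 to 6.73) and 10.6% (8.15 to 13.72) for untreated replicates 1 and 2. It was 16.3% (13.48 to 19.5) and 13.6% (11.9 to 15.5) for treated replicates 1 and 2. The interval of untreated replicate 2 overlapped those of both treated replicates. Among the 20000 strongest peaks of each list gained and lost regions differed by 0.19 percentage points. Nearly all of those regions had a weaker listed peak in another list, unlike the strong regions above.

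The strongest peaks were spread differently over chromosomes in the treated lists. Among the 20000 strongest peaks of each list, chromosome 5 held 10.8% and 10.7% in the untreated lists and 12.1% and 12.005% in the treated lists. Chromosome 11 rose in share from 8.71% and 9.24% to 9.69% and 9.67%. Chromosome 19 held 4.20% and 4.74% in the untreated and 3.51% and 3.58% in the treated lists, and chromosome 17 held 4.88% and 5.24% against 4.31% and 4.35%. These falls did not hold over all peaks. There the mean shares of chromosomes 19 and 17 were higher in the treated lists by 0.288 and 0.137 percentage points, and the groups overlapped. Among the 20000 strongest peaks, both treated lists were above both untreated lists in 6 chromosomes and below both in 9. Chance would give 3.83 of 23 for each on average if the libraries were exchangeable. Shares of chromosomes depend on each other, so the spread around that number is not known. Over all peaks, 1 chromosome was above and 3 were below. The strongest region in all 4 lists, on chromosome 1 from 121484500 to 121485511 next to the centromere, had a coverage of 452 and 526 in the untreated and 721 and 422 in the treated libraries.

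More peaks in the treated lists. Deeper sequencing of the treated libraries is argued against by their background coverage, 0.980 of that of the untreated libraries, only if the peak-calling settings were shared. Those settings and the number of reads are not known. Flatter treated libraries, with more weak and fewer strong peaks, remain open: peaks with a coverage of at least 10 were 0.822 times as many in the treated lists, but treated replicate 2, with 115284, lay between the untreated libraries. A wider set of accessible sites after treatment is named by the design and was not tested apart from this.

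Different places of gained and lost regions. A difference in background between libraries that also separates libraries of the same group cannot be told apart from other explanations by the relation over 5 Mb windows (Spearman rho 0.71), since shared libraries gave 0.68 from regions in 1 list only. It was not excluded for all gained regions near chromosome ends, whose share exceeded that of regions shared by untreated replicate 2 and treated replicate 1 by 0.851 percentage points (95% interval −0.247 to 1.93). Strong gained regions exceeded the 4 crossed classes together, which had 7.66% near an end (3.64% to 8.36% in each), by 18.5 points (14.0 to 23.005), but most of these were of untreated replicate 1 and treated replicate 2. Against the 36 strong regions of untreated replicate 2 and treated replicate 1 the explanation cannot be told apart from others, as the excess was 17.9 points (3.91 to 24.6) within 5 Mb and 25.1 (10.4 to 33.04) within 10 Mb, but 9.09 (−3.80 to 14.3) within 2 Mb, and among the 20000 strongest peaks the 1605 gained regions exceeded the 455 regions of that class by 0.757 (−2.75 to 3.78). The intervals cover counting error only, and the treatment and GC content stay open as untested.

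Different chromosomes of the strongest peaks. Lower peaks over background in the treated libraries cannot be told apart from other explanations: over all chromosomes, treated replicate 2 lay at 0.890 (95% interval 0.659 to 1.03) of the way from untreated replicate 2 to treated replicate 1, and at 0.938 (0.560 to 1.55) for chromosomes 5 and 11, while its median coverage lay at 0.286, and both intervals reach below the limit of 0.75 set for excluding it. For chromosomes 17 and 19 the joint share was 0.895 percentage points (0.320 to 1.47) higher in untreated replicate 2 than in untreated replicate 1, although its peaks were lower, but a difference between 2 single libraries excludes nothing. Fewer copies of chromosomes 17 and 19 were not excluded by their share of all peaks. It was 7.65% and 8.55% in untreated replicates 1 and 2, and 8.71% and 8.33% in treated replicates 1 and 2, so the groups overlapped. The log2 ratio of the mean shares was 0.074 over all peaks, against −0.27 among the strongest, so a fall of that size was not seen there. More copies of chromosomes 5 and 11 cannot be told apart from other explanations, because the lower treated share of all peaks exceeded the higher untreated share by 0.133 points with an interval of −0.0730 to 0.339. The treatment itself stays open and was not tested apart from these.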
